A study of Caenorhabditis elegans with 3 samples.

How the data were processed

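The series measured polyadenylated RNA of Caenorhabditis elegans, strain N2, by nanopore direct RNA sequencing. In this method native RNA strands are read without copying into cDNA or amplification. There were 3 libraries: mixed-stage embryo, L1 larva (the larval stage that follows hatching) and young adult, with 1 library per stage and no replicates. Per the labels' protocols, RNA was extracted with TRIzol, mRNA was purified on magnetic beads, and libraries were sequenced on a MinION with an R9.4.1 flow cell under MinKNOW 2.1, with base-calling in Albacore 2.0.1. The submitters' processing notes name minimap2 2.14. The genome build, the annotation, the tool that grouped reads into isoforms and any filters are not given in the sources used here.

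The deposited series table holds estimated counts: for each of 207067 isoform rows of 19194 genes, the authors' estimated reads in each library and over the 3 libraries together, not scaled for depth. Most estimated counts are fractional, as would arise if reads that match several isoforms were split between them, but how reads were assigned is not given. Of the rows, 25422 carry a transcript name of an annotation and 181645 carry the identifier of a read, and a row of either kind can hold no reads. The names give no exon structure, so isoforms known only by a read identifier could be counted but not described. A placeholder of 1e-08 was taken as 0. The 3 library values of a row did not sum to the pooled value in 613 rows, which together hold 235.9 reads. In 93.0% of 5000 sampled rows the split of the pooled value over libraries was a ratio of whole numbers up to 200 (within 1e-05), against 0.0% of random splits. This fits library values made by multiplying a pooled estimate by the proportion of matching reads per library, and isoform differences between libraries could be altered by that step.

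The deposited per-sample tables give a coverage signal per gene in a column headed Cpm. It equals the estimated reads of the series table multiplied by 1.326721 in each of the 3 libraries, for 15323 of 15323 genes, and its sums were 1249382 for embryo, 1349356 for L1 and 2137413 for young adult. The column is therefore not scaled to its own library, and it was used here only for this comparison of the files. Among the per-sample gene symbols 10 had turned into dates, and these were replaced from the names table. Gene symbols otherwise follow the deposited tables. Gene positions, gene types and transcript lengths come from Ensembl release 115 (WBcel235), and no coordinates are taken from the deposited files.

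For gene-level comparisons, estimated counts were summed over a gene's isoforms and rounded to whole reads, and a gene's read share is its reads divided by the library total. The ratio of 2 read shares is given with its exact conditional binomial (Clopper-Pearson) 95% interval. Genes with at least 20 reads over the 2 libraries were compared, and a gene is called higher or lower where the bound nearest to 1 is at least 2-fold from 1. These intervals cover counting error only and compare libraries, not stages, so no p-value is given. Where a library had 0 reads, the fold is a lower bound against 3 reads in that library. Log2 ratios have 0.5 read added to both libraries. For 29 gene lists fixed before the data were examined, the median log2 ratio over members with enough reads is set beside the medians of 10000 random lists of the same size matched on mean read share in 20 bins. A list stands apart where its median lies under the 2.5 or over the 97.5 percentile of the random lists.

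Named genes were chosen by a rule fixed before the data were examined. For each pair of libraries it took the 8 genes per direction whose nearest bound was farthest from 1, among genes with at least 100 reads in the higher library, and for each list the 4 members with most reads over the 3 libraries. For isoforms it took the 10 genes with the largest difference in share of the leading isoform, with intervals apart and at least 100 reads in both libraries, and the 3 isoforms with most reads among those seen in 1 library only. Members of near-identical families (vitellogenins, major sperm proteins, some collagens, tubulins and actins) can share reads, so their single values are uncertain.

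Isoforms were counted as detected from 2 reads, as deposited and after thinning each library to the shallowest in 20 draws. Isoforms seen in 1 library only had at least 5 reads there and 0 in both others. A leading isoform is the row with most reads of a gene that has at least 20 reads in each of 2 libraries.

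Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 for scaling factors. The comparison was tested on simulated reads drawn from the real library totals. In the L1 and embryo simulation 0 of 7895 unchanged genes were called, with 32 of 40 genes at 4-fold and 40 of 40 at 8-fold. In the young adult and L1 simulation the values were 0 of 8629, 36 of 40 and 40 of 40. In the young adult and embryo simulation they were 0 of 8584, 34 of 40 and 40 of 40. Of genes set lower, the calls were at 0.25-fold 28 of 34, 21 of 31 and 19 of 32 in the same order, and at 0.125-fold 29 of 30, 34 of 36 and 28 of 29. In simulated isoform tables with 100 reads per gene and library, 87 of 100 swapped leading isoforms were found and 0 of 900 unswapped genes were called.

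The alternatives tried were edgeR TMM factors, DESeq2 median-of-ratios size factors, a total without the 50 genes with most reads, other read minimums, other fold rules, a 99.9% interval, libraries thinned to equal depth, only annotated isoform names, 2 reads added, and other minimums for isoforms. Counts of genes higher than in both other libraries were repeated with TMM and DESeq2 factors, and the comparison of collagens with sperm proteins with equal read minimums for both, alternatives chosen after seeing the data. Merging isoforms that are truncated parts of others was planned and not run, because it needs exon structures.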

Results

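Poly-A RNA of mixed-stage embryos, L1 larvae and young adults of Caenorhabditis elegans was sequenced as native RNA on a nanopore device, with 1 library per stage. The embryo library held 941707 estimated reads, the L1 library 1017061 and the young adult library 1611049. Reads were seen for 12013 genes in the embryo library, 13188 in the L1 library and 12614 in the young adult library. A gene with 0 reads could still hold up to 3 reads, which is 3.19 reads in every 1000000 in the embryo library, 2.95 in the L1 library and 1.86 in the young adult library. The 50 genes with most reads took 14% of embryo reads, 32.4% of L1 reads and 24.8% of young adult reads. The largest gene of the embryo library was mitochondrial ctc-2 with 10499 reads, that of the L1 library ant-1.1, an ADP/ATP carrier gene, with 13135, and that of the young adult library rla-0, a ribosomal stalk gene, with 12668. No replicate check exists for any difference described here, and intervals are 95% intervals for counting error only. The series title states an interest in transcript complexity over development, so pairs of stages are compared for genes and then for isoforms.

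Ribosomal protein genes, neuropeptide genes and genes of intestinal digestion took larger read shares in the L1 library than in the embryo library, while genes of cell division, chromatin, splicing and the embryonic body plan took smaller ones. Ribosomal protein genes held 33.82% of L1 reads against 11.19% of embryo reads, and 67 of 78 measured members were higher and 1 lower in the L1 library. Among them rps-8 was 3.51-fold higher (3.37 to 3.67), rla-0 3.37-fold (3.21 to 3.53) and rpl-3 3.69-fold (3.52 to 3.87). Of 51 measured neuropeptide genes 49 were higher, including flp-9 at 43.1-fold (27.8 to 71) and flp-1 at 27.5-fold (18.2 to 43.7). The peptide-processing genes egl-3 and egl-21, listed with neurons, were 45.4-fold (25.8 to 88.3) and 27.5-fold (20.6 to 37.5) higher, although the neuron list as a whole had 6 members higher and 6 lower of 26. Of 43 genes of intestinal digestion and lysosomes 33 were higher and 1 lower. Examples were the lipid-binding far-2 at 51.3-fold (34.9 to 78.8), the protease gene asp-6 at 18.4-fold (15.4 to 22.2) and the lectin gene clec-47 at least 260-fold. Of 35 fat metabolism genes 17 were higher and 6 lower, with the desaturase gene fat-2 higher by a log2 ratio of 6.78 and hacd-1 at least 275-fold higher.

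Genes of the dividing embryo were lower in the L1 library. Of 48 cell cycle and replication genes 41 were lower and 0 higher, and their joint share was 0.12% in the L1 library against 1.16% in the embryo library. The B-type cyclin gene cyb-3 was 27.5-fold lower (21.7 to 35.2), the ribonucleotide reductase gene rnr-2 15.6-fold and pcn-1, which encodes the replication clamp PCNA, 15.4-fold (11.8 to 20.3). Of 43 splicing genes 38 were lower, including the SR protein genes rsp-3 at 10.2-fold (8.44 to 12.5) and rsp-6 at 14.1-fold. Of 11 linker and replacement histone genes 9 were lower and 1 higher, with his-24 at 18-fold (15.5 to 21) and htz-1 at 15.4-fold (13.2 to 18.1). Maternal determinants were lower for 18 of 24 genes, among them pos-1 at 9.91-fold (7.79 to 12.8) and mex-5 at 9.28-fold (6.22 to 14.4). Zygotic lineage transcription factors were lower for 13 of 19 genes, among them lin-26 at 3-fold (2.44 to 3.72), not called with TMM factors, and elt-1 at 7.33-fold (4.16 to 13.9). Heterochronic genes were lower for 6 of 8. Molting genes were lower for 14 of 21 and higher for 1, with noah-1 at 23.2-fold lower (14.8 to 38.3), and other hypodermis and cuticle genes were lower for 15 of 22.

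Collagen genes divided the same 2 libraries. Of 93 measured cuticle collagens 64 were higher and 13 lower in the L1 library, yet their joint share was 1.05% there and 1.3% in the embryo library. The lower members included the abundant embryonic collagens dpy-14 at 78-fold lower and dpy-17 at 58.7-fold lower (43.4 to 81.3). Of the muscle lists, body wall muscle had 6 members higher and 17 lower of 37, turning to 10 higher and 4 lower with TMM factors, while pharyngeal muscle had 3 higher of 7. Stress and DAF-16 target genes had 10 higher and 4 lower of 24. The heat shock gene hsp-16.41 was 18.6-fold lower (13.5 to 26.3), while the glycolytic gpd-3, on the same list, was 3.43-fold higher (3.09 to 3.82). Of 17 genes of the glyoxylate, trehalose and gluconeogenesis list 3 were higher, or 9 with TMM factors. Adult germline transcripts were few in both libraries but not equal. Major sperm protein genes had 609 reads in the L1 library against 3 in the embryo library. Of 28 such genes 15 had enough reads, and 15 of 15 were higher in the L1 library. They passed the read minimum through their L1 reads, so that count largely follows from the filter. Oocyte and eggshell genes as a list had 3 higher and 8 lower of 28, turning to 5 higher and 3 lower with TMM factors, with 1379 L1 reads against 2085 embryo reads. Within it the vitelline layer gene perm-4 was at least 61.4-fold higher and, among yolk genes, vit-6 at least 60.8-fold higher in the L1 library.

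By the bound nearest to 1, the single genes that differed most between these libraries were led by tts-1 (F09E10.11; chromosome X, 1504131 to 1504841, minus strand, WBcel235), a non-coding RNA with 12682 reads in the L1 library and 18 in the embryo library, 652-fold higher (413 to 1100). T22F3.11 (chromosome V, 3612158 to 3614553, minus strand) had 1358 reads in the L1 library and 0 in the embryo library, at least 419-fold higher. The lipid-binding far-7 was at least 295-fold higher, nspc-20 at least 262-fold, T26H5.9 at least 230-fold and C49G7.3 at least 214-fold. In the other direction the lectin gene clec-266 was 363-fold lower, the Skp1-related skr-7 205-fold lower (87.4 to 632), the transthyretin-related ttr-50 lower by a log2 ratio of -7.12 and C01G6.3 153-fold lower (80.5 to 336). The hatching protease gene hch-1 (chromosome X, 14696411 to 14699977) had 266 embryo reads and 0 in the L1 library, at least 95.8-fold lower. EEED8.15 was at least 85.7-fold lower, clec-196, with 1 L1 read, 373-fold lower (66.4 to 14800), and the cuticlin gene cut-2 89.7-fold lower.

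Over 8382 genes with enough reads, 1120 were higher and 2771 lower in the L1 library, so 71.2% of called genes were lower, and the median log2 ratio of all of them was -1.14. With edgeR TMM factors the median moved by 0.87 and the split became 1574 higher and 1132 lower, or 41.8% lower, and with DESeq2 size factors the median moved by 0.92 and 40.2% were lower. Relative to matched random lists, which share this shift, 10 of 28 lists lay above and 8 below the random range. The ribosomal list had a median log2 ratio of 1.55 against 0.08 for random lists, and the cell cycle list -2.86 against -1.24. Lists within the random range were oocyte and eggshell, germ granule, meiotic axis, tubulins, body wall muscle, neurons, chaperones, translation factors, mitochondrially encoded genes and nuclear oxidative phosphorylation genes. Their calls depended on scaling: for chaperones 3 were higher and 19 lower of 36, but 4 and 4 with TMM factors. With TMM factors the list medians changed sign for mitochondrially encoded genes (-0.38 to 0.49), neurons (-0.47 to 0.40) and nuclear oxidative phosphorylation genes (-0.16 to 0.71). Several lists below the random range had fewer members called lower with TMM factors: 28 of 48 cell cycle genes, 20 of 43 splicing genes, 10 of 24 maternal determinants, 7 of 19 zygotic factors and 3 of 8 heterochronic genes.

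**Figure D1:**
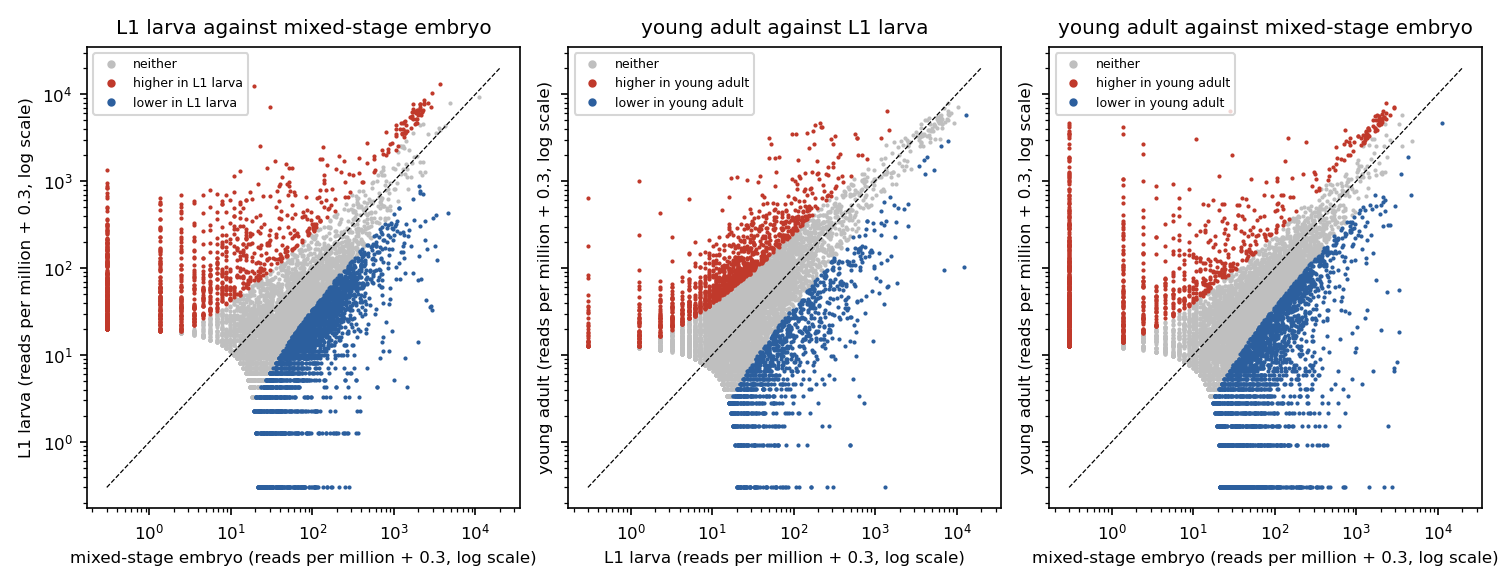
Reads of each gene per 1000000 library reads in pairs of libraries, on log axes with a small constant added so that 0 can be drawn. Each point is a gene with at least 20 reads in the pair, coloured where the bound of its 95% counting interval is at least 2-fold from 1. The dashed line marks equal shares. In the left panel 1120 genes were higher and 2771 lower in the L1 library.

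Germline, yolk and some adult cuticle transcripts took larger shares in the young adult library than in the L1 library, and neuropeptide and neuronal transcripts took smaller ones. All 6 vitellogenin genes, which encode yolk proteins, were higher, with vit-6 at 8.87-fold (7.68 to 10.3) and vit-2 at 5.48-fold (4.83 to 6.24). Of 26 measured major sperm protein genes 25 were higher and 0 lower, including msp-36 at 11.8-fold and msp-152 at 16.6-fold (11.5 to 25), and 16 of 23 other sperm genes were higher. Oocyte and eggshell genes were higher for 25 of 29, with the chondroitin proteoglycan gene cpg-2 at 9-fold (7.49 to 10.9) and perm-4 at 6.15-fold (5.31 to 7.15). Germ granule and germline RNA regulators were higher for 17 of 26, among them the translational repressor gene gld-1 at 15.3-fold (11.3 to 21.2), and meiotic axis genes for 8 of 20. Maternal determinants were higher for 13 of 22, such as mex-5 at 10.8-fold. Cell cycle genes were higher for 20 of 46, with cyb-1 at 7.56-fold (5.57 to 10.5), and splicing genes for 13 of 40, with 4 lower.

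Neuropeptide genes were lower for 48 of 52 in the young adult library, including flp-9 at 16.8-fold lower (13.5 to 21.1) and flp-14 at 14.5-fold lower. Of 21 neuronal genes 11 were lower and 1 higher, with egl-3 at 62.1-fold lower. Pharyngeal muscle genes were lower for 4 of 6, molting genes for 9 of 17, and stress and DAF-16 targets for 8 of 25, with 2 higher. Intestinal digestion genes went both ways, with 8 higher and 12 lower of 45: far-2 was 4.47-fold higher (4.23 to 4.73) and the metallothionein gene mtl-1 206-fold lower (87.8 to 636). Of 12 mitochondrially encoded genes 4 were lower, among them ctc-3 at 2.73-fold (2.63 to 2.83) and ctb-1 at 2.26-fold (2.16 to 2.37). Ribosomal protein genes held 28.47% of young adult reads and 33.82% of L1 reads, and 3 of 78 were higher and 4 lower. Of 12 tubulins 2 were higher and 4 lower, and of 38 fat metabolism genes 8 were higher and 8 lower.

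Cuticle collagens held 6.44% of young adult reads against 1.05% of L1 reads, with 32 members higher, 34 lower and 32 called neither way of 98. Collagen col-124 was 62.8-fold higher (47.7 to 84.4), col-80 higher by a log2 ratio of 4.59 and col-122 21.9-fold higher (19.2 to 25.3). On the lower side, col-36 had 312 L1 reads and 0 young adult reads, and col-37, outside the fixed list, 259 and 0, with log2 ratios of -9.95 and -9.68. Genes named on the higher side by the same bound included the yolk genes vit-3, at least 214-fold higher, vit-1, at least 60.2-fold, and vit-4, with 1 L1 read, 1010-fold (180 to 39800). These genes have near-identical copies among the vitellogenins that did have L1 reads, so their single ratios are uncertain. Y47G6A.33 was 220-fold higher (60.7 to 1820), T13F3.6 higher by a log2 ratio of 6.83, the folate transporter gene folt-2 241-fold (42.9 to 9530) and C45B2.1 65.2-fold. On the lower side, T22F3.11 had 1358 L1 reads and 0 young adult reads, at least 717-fold lower (log2 ratio -12.07), and tts-1 was 120-fold lower. With 507 and 498 L1 reads and 1 young adult read, F46C5.1 and C23G10.11 were lower by log2 ratios of -9.07 and -9.04, and T26H5.9, with 745 and 4 reads, by -8.04.

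Of 8043 genes with enough reads in this pair, 1163 were higher and 1142 lower in the young adult library, and the median log2 ratio was 0.32. TMM factors moved that median by -0.07 and gave 1056 higher and 1202 lower. Of 29 lists 9 lay above and 9 below the range of random lists, with medians of 3.56 for major sperm proteins and -3.66 for neuropeptides.

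Against the embryo library, the young adult library had larger shares of yolk, sperm, eggshell, adult collagen, digestive and ribosomal transcripts and smaller shares of lineage regulators, embryonic cuticle and chromatin transcripts. Vitellogenin genes had 8918 young adult reads and 0 embryo reads, together at least 1740-fold higher. Major sperm protein genes had 11718 reads against 3, and 26 of 26 measured members were higher. They passed the read minimum through their young adult reads, so that count largely follows from the filter. Other sperm genes were higher for 19 of 20, with 4132 young adult reads against 21 embryo reads, so that count too largely follows from the filter. Oocyte and eggshell genes were higher for 16 of 29 and lower for 1, with cpg-2 at 10.3-fold (8.45 to 12.8) and cpg-3 at 23.5-fold (15.4 to 37.6). Germ granule genes were higher for 10 of 29 and lower for 2, such as car-1 at 4.17-fold higher (3.69 to 4.74). Ribosomal protein genes were higher for 66 of 78 and lower for 1, intestinal digestion genes for 30 of 40 and 1, and fat metabolism genes for 15 of 34 and 4. Of 38 neuropeptide genes 8 were higher and 1 lower, or 15 and 0 with TMM factors.

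Of 82 cuticle collagens 49 were higher and 22 lower. The 8 genes named on the higher side, by the bound nearest to 1, were all collagens with 0 embryo reads. Of these, col-122 was at least 1460-fold higher, col-80 at least 1400-fold, col-178 at least 1300-fold and col-140 at least 1170-fold. The others were col-20 at least 1120-fold, col-129 at least 1090-fold, col-93 at least 1080-fold and col-119 at least 1050-fold higher. Among the 8 named on the lower side, 4 were collagens. The gene dpy-14 (chromosome I, 6843589 to 6845142) had 2600 embryo reads and 0 young adult reads, at least 1480-fold lower, and dpy-17 was 2000-fold lower (552 to 16500) on 2 young adult reads. Collagen col-165 had 687 embryo reads and 0 young adult reads, and col-74 665 and 0, at least 379-fold lower. The linker histone gene hil-7 was at least 1160-fold lower, the lectin gene clec-266 at least 766-fold, and the cuticlin genes cut-3 and cut-2 at least 365-fold and 469-fold (255 to 979).

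Zygotic lineage transcription factors were lower for 18 of 18 measured genes in the young adult library, or 15 with TMM factors, with ceh-13 at 48.9-fold (20.5 to 153) and elt-1 at 23.2-fold (10.8 to 59.3). The list had 1288 embryo reads against 267 young adult reads, so members passed the read minimum mainly through embryo reads. That count therefore follows in part from the filter. Heterochronic genes were lower for 8 of 9 and higher for 1, with ain-1 at 39.4-fold lower (22.2 to 77.1). Molting genes were lower for 15 of 21 and higher for 1, other hypodermis genes lower for 15 of 19, and histone variant genes lower for 7 of 11 and higher for 1, with his-24 at 397-fold lower (232 to 746). Cell cycle genes were lower for 26 of 49 and splicing genes for 26 of 42. Mitochondrially encoded genes were lower for 8 of 12, including ctc-2 at 2.41-fold (2.34 to 2.48), not called with TMM factors, and body wall muscle genes for 17 of 36, with 6 higher, but 8 and 8 with TMM factors. In all, 1140 genes were higher and 2533 lower of 8636, or 69% lower, around a median log2 ratio of -0.71. TMM factors moved the median by 0.80 and gave 1690 higher and 1491 lower, or 46.9% lower. With them 11 of 49 cell cycle genes, 13 of 42 splicing genes and 3 of 12 mitochondrially encoded genes were lower. Medians changed sign with TMM factors for chaperones (-0.63 to 0.17), the glyoxylate list (-0.06 to 0.74), pharyngeal muscle (-0.71 to 0.09) and translation factors (-0.25 to 0.54). Lists that stood apart from random lists numbered 11 above and 10 below of 29.

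**Figure D2:**
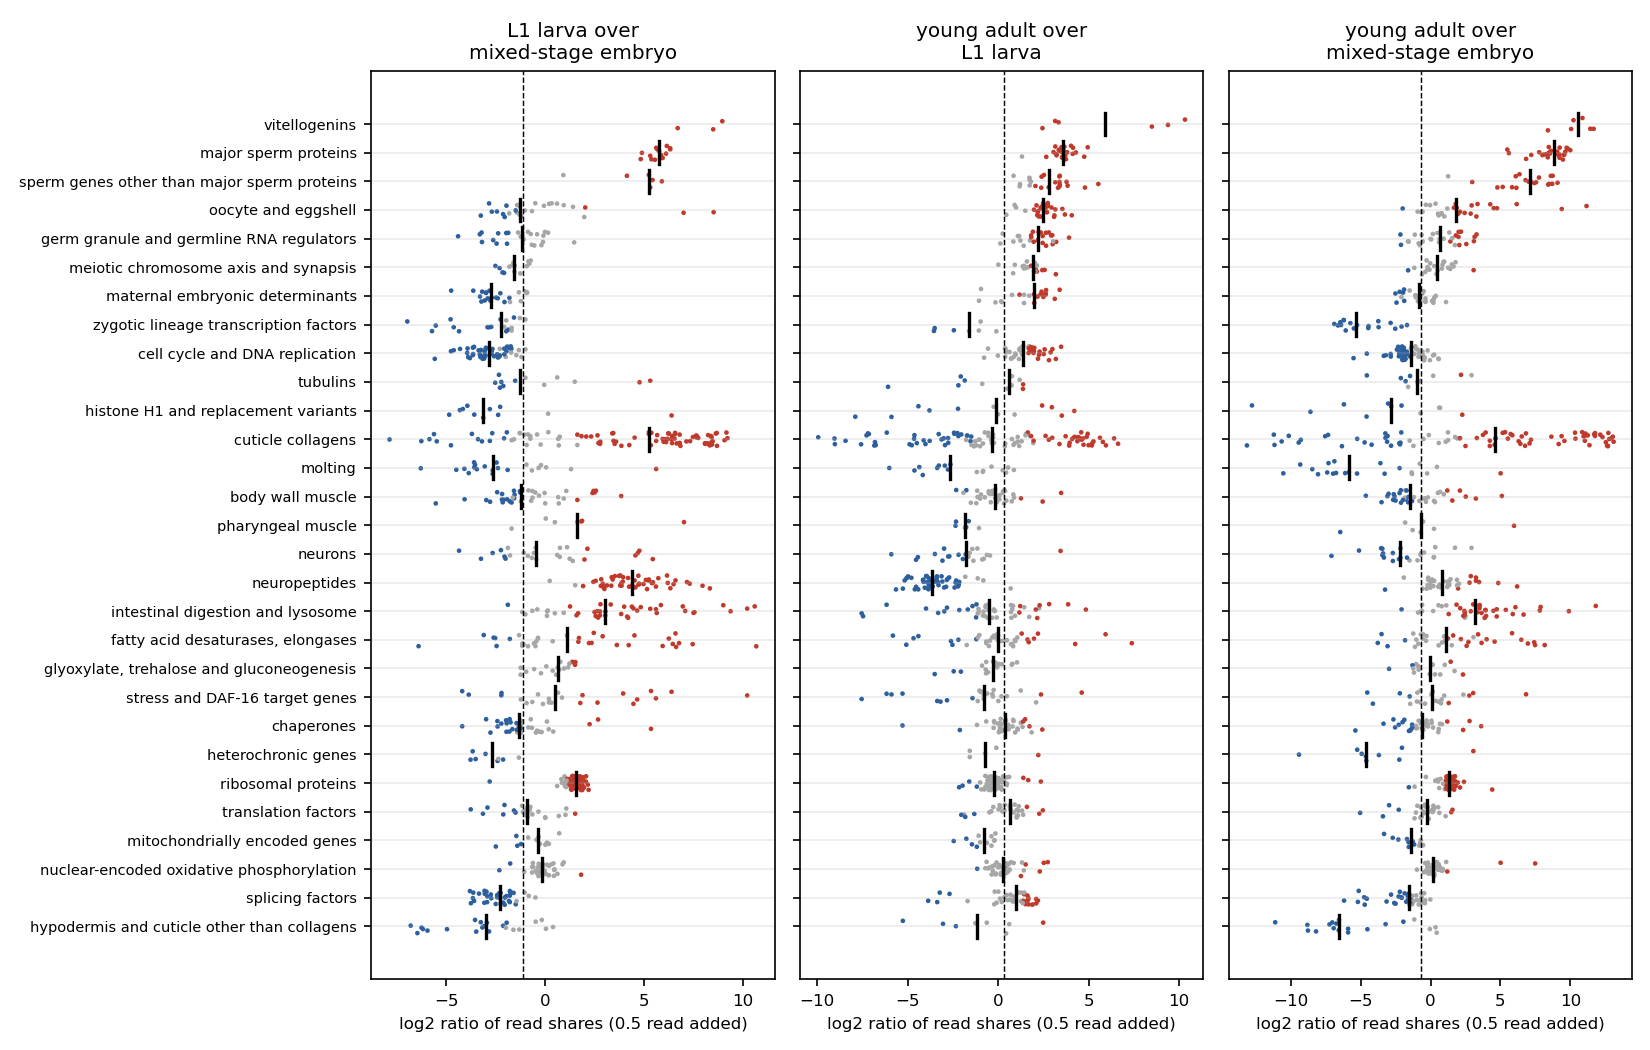
Log2 ratios of read shares for members of the 29 gene lists in 3 pairs of libraries, with 0.5 read added to both libraries. Points are genes, red where called higher and blue where called lower, black bars are list medians, and dashed lines are the median of all compared genes. Neuropeptides have a median of 4.41 in the left panel and -3.66 in the middle panel.

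Counted against both other stages, 1672 genes were higher in the embryo library, 561 in the L1 library and 469 in the young adult library. With TMM factors, tried after seeing the data, the counts were 718, 741 and 613, so the embryo excess depended on scaling. The genes called by read share held 30.3% of embryo reads, 16.8% of L1 reads and 17.6% of young adult reads.

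Isoforms were most numerous in the embryo library in total, but not in the gene with most of them. That gene was ant-1.1 in the L1 and young adult libraries, with 215 and 211 isoforms, and in the embryo library the poly-A binding protein gene pab-1, with fewer than either. With at least 2 reads, 60113 isoforms of 10230 genes were detected in the embryo library, 47815 of 10846 genes in the L1 library and 54660 of 10596 genes in the young adult library. The embryo library was the shallowest, and with the others thinned to its 937172 isoform reads the counts were 45755 for L1 and 40912 for young adult. In 3308 genes compared at equal depth per gene, the mean was 12.48 isoforms in the embryo library, 12.13 in the L1 library and 10.92 in the young adult library. More isoforms were seen in the embryo than in the young adult library for 1981 of these genes, and fewer for 751, while embryo and L1 were closer, with 1365 genes higher in the embryo library and 1251 in the L1 library. Curves were still climbing at full depth, so these counts depend on depth. Isoforms that are truncated parts of others were not merged, so the counts can include them, and their number in each library is not known. The counts therefore cannot be read as numbers of distinct full transcripts.

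**Figure D3:**
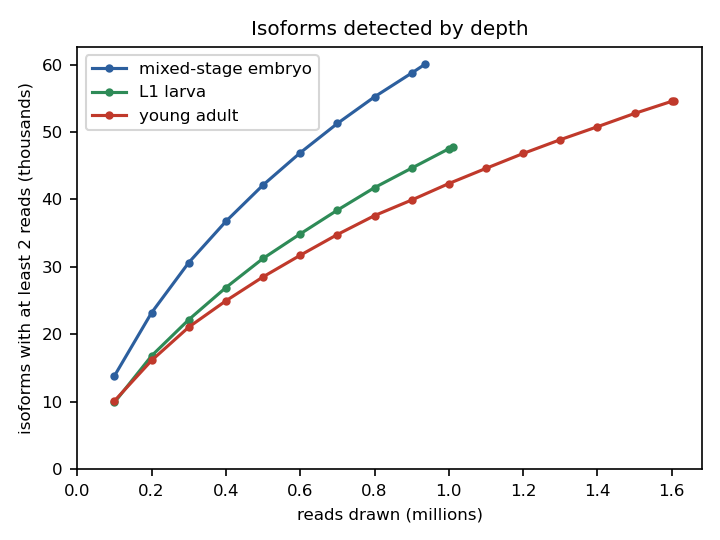
Isoforms with at least 2 reads, in units of 1000, against the number of reads drawn from each library, in units of 1000000. Points are draws at fixed depths, and the last point is the full library, with 60113 isoforms for embryo, 47815 for L1 larva and 54660 for young adult.

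Most isoforms carried read identifiers. Annotated transcript names made up 10.1% (9.91 to 10.3) of embryo isoforms with reads, 10.62% (10.41 to 10.83) of L1 isoforms and 10.43% (10.23 to 10.63) of young adult isoforms. They held 17%, 15.4% and 17.9% of reads. An annotated name led 550 of 6377 embryo genes with at least 20 reads, 452 of 4906 L1 genes and 709 of 6202 young adult genes.

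Isoforms seen in 1 library only numbered 691 in the embryo library, 425 in the L1 library and 338 in the young adult library. With libraries thinned to the shallowest these counts were 859, 534 and 210, so they depend on depth. The genes with most such reads had few or no reads in the other stages: Y71A12B.11, F56A8.8 and sdz-28 led in the embryo library, the last with 91 reads of the isoform. An isoform of T22F3.11 with 469 reads led in the L1 library, beside transcript C27H5.5c.1 of col-36 with 226. In the young adult library vit-3 led with 461 reads of its transcript F59D8.1.1 and 206 of another isoform, beside C14F11.4 with 92, a gene with 3 L1 reads. In genes with at least 20 reads in each library 4 embryo, 21 L1 and 3 young adult isoforms were of this kind, against 167.4, 104.4 and 212.9 in reads shared out at random within genes. The observed isoforms could not hold even a fraction of a read in the other libraries, a stricter rule than in the draws. The numbers are therefore not directly comparable. Among the few observed isoforms, named after their values were seen, transcript C14F5.3c.5 of the troponin gene tnt-3 had 11 embryo reads. Transcript C31C9.1b.1 of tag-10 had 14 young adult reads. The alcohol dehydrogenase gene sodh-1 had isoforms of 14, 14 and 12 L1 reads. That gene had 7219 L1 reads against 28 embryo and 151 young adult reads. Isoforms holding so small a part of its reads could go unseen in the other libraries at equal isoform shares. Their absence there therefore cannot show a difference in isoform use.

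The leading isoform differed between L1 and embryo in 384 of 3710 genes, between young adult and L1 in 511 of 3971 and between young adult and embryo in 507 of 4600. Of these, 17, 48 and 44 genes had intervals apart for both isoforms, against means of 0.7, 0.9 and 0.6 in reads drawn by chance. In F15G9.1 (chromosome X, 9706384 to 9708566) the leading young adult isoform held 41.4% (34.9 to 48.1) of the gene's young adult reads and 0.8% (0 to 4.2) of its embryo reads, and the leading embryo isoform 7.5% (4.4 to 11.7) and 72.3% (63.8 to 79.8). In dss-1, a proteasome subunit gene, the leading embryo isoform held 50.6% (42.7 to 58.4) of embryo reads and 11.5% (6.3 to 18.9) of young adult reads. The leading young adult isoform of prmt-1, an arginine methyltransferase gene, held 45.8% (42 to 49.7) of young adult and 18.7% (15.6 to 22.1) of L1 reads. For snr-2, a spliceosomal Sm protein gene, it held 57.2% (52.9 to 61.3) of young adult and 21.6% (18.6 to 25) of embryo reads. For the translation initiation gene eif-1 it held 56.3% (51.8 to 60.7) of young adult and 21.8% (16.3 to 28.1) of L1 reads. In hmg-1.2 the leading embryo isoform was the annotated transcript F47D12.4b.1 (chromosome III, 6280421 to 6282414, 5 exons, WBcel235), with 19.7% (16 to 23.8) of embryo and 1.7% (0.2 to 5.8) of young adult reads. C06G3.5, Y14H12B.1, W09C5.1 and pqn-53 also had intervals apart, with young adult leaders at 53.2%, 57.4%, 43.6% and 55.3% of young adult reads. More genes differed in leader by chance sampling, with means of 761.8, 724.4 and 768.0, than were observed, so counts without the interval rule hold no excess over sampling.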

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

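The 8 genes named per pair and direction kept their direction under both scalings by construction, since a scaling moves all genes of a pair alike and these lie far from 1. Of the list members given with a fold, lin-26 (L1 against embryo) and ctc-2 (young adult against embryo) were not called with TMM factors. Results with other values follow, and the cause was not tested unless the setting's own construction gives it. The percent of called genes that were lower in L1 than embryo was 41.8 with TMM and 40.2 with DESeq2 factors, with 1132 and 1078 genes lower. For young adult against embryo it was 46.9 and 45.4, with 1491 and 1447 lower and, with DESeq2 factors, 1737 higher. For young adult against L1, near even at first, it was 53.2 with TMM, 53.6 with DESeq2, 57.4 without the 50 genes with most reads, 56.6 with a minimum of 1 read, 55.1 with a stricter interval and 61.4 with a 4-fold bound, but 41.5 with a minimum of 50 reads and 45 with a 1.5-fold bound. With a 4-fold bound 739 genes were higher and 981 lower for L1 against embryo, 332 and 528 for young adult against L1, and 638 and 1321 for young adult against embryo. A 1.5-fold bound gave 1866 higher for young adult against L1, a stricter interval 635, and a minimum of 50 reads 710 lower. A stricter interval gave 1805 lower for L1 against embryo. Genes higher in embryo than in both others numbered 718 with TMM and 695 with DESeq2 factors, tried after seeing the data. Annotated isoforms alone, which hold fewer reads, gave 333 higher and 532 lower for L1 against embryo, 302 and 293 for young adult against L1, and 353 and 584 for young adult against embryo.

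Isoforms with at least 1 read numbered 94346 in embryo, 84644 in L1 and 88960 in young adult, and with at least 5 reads 29393, 22348 and 27857, of which 16.46%, 16.78% and 17.53% had annotated names. Isoforms seen in 1 library only were 1338, 906 and 670 from 3 reads, 260, 148 and, rounded, 1.3e2 from 10 reads, and 4, 21 and 3 in genes with at least 20 reads in each library. With libraries thinned to the shallowest the counts were 859, 534 and 210. Leading isoforms differed from 50 reads in, rounded, 1.5e2 genes for L1 against embryo, 229 for young adult against L1 and 268 for young adult against embryo, and in 695 for L1 against embryo and 811 for young adult against L1 from 10 reads. With stricter intervals 8, 19 and 15 genes had intervals apart. Merging truncated isoforms was not run, and no library could be left out, as each stage has 1.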

Other observations

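Gene classes by symbol, most of them outside the fixed lists, were looked at after the data were seen, as examples picked from screens of 91 symbol classes for L1 against embryo, 84 for young adult against L1 and 90 for young adult against embryo, so they are selected. F-box genes of the fbxb class, whose proteins select targets for ubiquitin ligases, were lower in the L1 than in the embryo library for 38 of 38 measured members and lower in the young adult library for 36 of 36, with 2078 embryo reads against 22 and 14. With TMM factors 36 of 38 and 36 of 36 were lower. Nearly all reads of the class were embryo reads, so members passed the read minimum through that library and the counts largely follow from the filter. The fbxc class was lower for 11 of 13 in the L1 library, and skr genes, Skp1-related partners of F-box proteins, for 12 of 18 with 2 higher. Homeobox genes of the ceh class were lower for 21 of 26 in the L1 library, or 9 with TMM factors. In the other direction, nspc genes had 1746 L1 reads against 1 embryo read, and 9 of 9 measured members were higher in the L1 library. They passed the read minimum through L1 reads, so that count likewise largely follows from the filter. Of 41 transthyretin-related ttr genes 28 were higher and 1 lower in the L1 library. Insulin-like ins genes were higher in L1 than embryo for 7 of 11 with 3 lower, and lower in young adult than L1 for 6 of 9 with 1 higher.

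Genes on the X chromosome, which is transcribed little in the germline, held 9.81% of embryo reads, 9.27% of L1 reads and 7.04% of young adult reads. The median log2 ratio of young adult over L1 was -0.71 for 895 X-linked genes and 0.44 for 7127 autosomal genes, and 25.4% of X-linked genes were lower against 12.7% of autosomal ones. Between L1 and embryo the medians were -1.13 and -1.15. Separately, 1681 isoform identifiers were listed under more than 1 gene and held 1.52% of reads. Of 1456 with both genes placed, 1362 joined genes within 10 kb on the same strand.

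Of the tests that follow, those on ribosomal reads and on adult transcripts were chosen after the result was seen, and those on transcript length and on isoform shares before.

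By read share more genes were lower than higher in the L1 library than in the embryo library, a pattern that turned with TMM factors (1574 higher, 1132 lower). A larger share of ribosomal protein reads is not the whole cause, since without those genes in either total the median log2 ratio of the others was still -0.73. By the median, transcript length is not the whole cause either: it was -0.64 in the third of genes with the shortest annotated transcripts and -1.41 in the longest. By the split of calls, 52.6% were lower among the shortest, near even, 75.5% in the middle and 89.4% in the longest. The split of calls was not part of the test chosen before, and the Spearman rank correlation of ratio with length over genes was -0.21. The split thus went with length, but how much of it length accounts for was not tested. Young adult against embryo had the same gradient, at 48.6%, 70.5% and 88.4% lower. Young adult against L1 had none, at 54.1%, 43.3% and 51.1%. The gradient thus set the embryo library apart from both others and was not particular to the L1 library. A difference in recovery of long RNA and the stages themselves stay open.

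Adult sperm, yolk and eggshell transcripts were present in the L1 library at 8.23% (7.58 to 8.93) of the young adult share for major sperm proteins, 11.27% (9.98 to 12.69) for other sperm genes, 9.31% (8.51 to 10.17) for vitellogenins and 15.79% (14.69 to 16.94) for eggshell and yolk receptor genes. Members varied, from 2.99 to 15.15% for sperm proteins and from 0 to 18.25% for vitellogenins. Young adult material of the same make-up would bring all adult transcripts at 1 ratio, and 21 collagens with 0 embryo and at least 1000 young adult reads stood at 4.37% (4.19 to 4.55), from 1.59 to 12.54%, or 0.53 times the sperm protein ratio. That filter favours low ratios: with a minimum of 100 young adult reads for both families the value was 0.59, and with a minimum of 1 read, which lets in larval collagens, 0.82, so the test does not settle the source. Carried-over young adults, adults of another age, remains of mothers and transcription in larvae stay open as possible explanations.

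Fewer genes than by chance sampling had another leading isoform without the interval rule. Leaders with intervals apart exceeded chance, at 17, 48 and 44 genes against 0.7, 0.9 and 0.6. Fewer isoforms than by chance were also seen in 1 library only. The observed isoforms met a stricter rule there than the random draws, so that gap cannot be read as spread below chance. If each row took its library split from all reads that match it, shared reads included, genes whose rows hold whole reads only would show at least the chance spread. The chi-square per degree of freedom in such genes was 0.38 for L1 against embryo (9 genes, chance range 0.40 to 1.87), 1.64 for young adult against L1 (13 genes, chance range 0.46 to 1.75) and 0.45 for young adult against embryo (12 genes, chance range 0.44 to 1.78). Only the lowest of these lies outside its range, which with so few genes argues weakly against the account. In genes with any fractional pooled count the value was 0.54, 2.55 and 1.48. The chance spread of whole reads need not hold for fractional counts, so these values cannot show spread above or below chance. How the deposited library values were made may still limit isoform comparisons, and no biological explanation was tested.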
